A study of Mus musculus with 21 samples.

How the data were processed

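RNA was sequenced from 3 mouse cell lines in 21 samples. Per the labels, total RNA was isolated with RNeasy columns, ribosomal RNA was removed with Ribo-Zero Gold, and libraries were made with a strand-specific SureSelect kit. Per the labels' processing notes, reads were trimmed with cutadapt, aligned to the mm10 genome with HISAT2, assembled and quantified with StringTie, and analysed further with edgeR, with no versions given. The labels do not state which strand setting was used for counting or which annotation release was used. Esrp2-as lies antisense to Esrp2 and overlaps it, so the values of both genes are uncertain where reads from the overlap could be split between them.

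The gene and transcript tables hold expected counts, which StringTie estimates from read coverage, per the labels' processing notes and the deposited whole numbers. They cover 48440 genes and 117667 transcripts, and both give the same total in all 21 columns. The other 2 tables hold a normalised signal: deposited CPM values, scaled by an effective library size with low-abundance features left out, for 21940 genes and 69169 transcripts. Column totals of these deposited signals ran from 925532 to 1053335 for genes and from 914804 to 1107996 for transcripts. Of each of these kinds of signal, 1 column of values matched no sample and was not used here. Its name gave the lane whose labelled samples were all M6, so that lane also held a library of unknown line. The signal tables were only compared with the counts. Every comparison was computed from the counts.

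Gene identifiers were looked up in GENCODE release M21 on GRCm38, where 48058 gene identifiers and 116824 transcript identifiers matched. The unmatched identifiers held 0.0515% of gene counts and 0.196% of transcript counts. Coordinates are those of GENCODE M21 on GRCm38, counted from 1.

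The 21 columns stood for 14 biological replicates in 6 groups, and columns that the labels call technical replicates were summed. For 5 libraries the technical replicates were the same library on 2 lanes. For genes with 50 to 2000 counts the variance between these lanes was 2.83 to 3.18 times binomial counting error. The technical replicates of M6 replicate 2 also carried different library codes, and there the ratio was 4.82 to 6.82 over 3 pairs. For genes over 2000 counts it was 34.0 to 67.0 in these pairs, against 5.36 to 6.18 between lanes of the same library. Whether these columns are repeats of the same preparation is not known, and they were summed as the labels state. Summed totals ran from 34892461 to 328493417 counts. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Levels of replicates and groups are given as CPM of the effective library size, the total scaled by its TMM factor, and levels of single columns as CPM of the column's total, in each case with the standard deviation (SD) between replicates.

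Tests of genes used edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group, which left 21237, and libraries were scaled with TMM factors. A single quasi-likelihood model with robust dispersion was fitted over all 6 groups with 8 residual degrees of freedom, so the groups shared their estimate of spread. The biological coefficient of variation was 0.324. P values were adjusted over all genes tested by the method of Benjamini and Hochberg, and an adjusted p under 0.05 was counted as a call. Each standard error (SE) is the log2 fold change over the square root of its F statistic. There were 6 contrasts: knockdown against control in M6, overexpression against control in M27H4 and in 3T3-L1, the difference between these overexpression effects, M27H4 control against M6 control, and the M6 knockdown effect minus the M27H4 overexpression effect.

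A group of 29 gene lists was tested with camera at a preset correlation of 0.01 between genes, beside camera with an estimated correlation and fry, all adjusted over the 29 lists. The gene lists, the contrasts, the tests and the rule for named genes were fixed before the data were examined. Under that rule Esrp2-as and Esrp2 were always named. Among genes with an adjusted p under 0.05, a mean of at least 1 CPM, separate replicate ranges and an ordinary symbol, the 8 largest changes up and down were named. Up to 4 members with the smallest p were named from each list called by camera, or from the 5 lists with the smallest p where none was called. Where fewer than 4 genes qualified, the 4 genes with the smallest p were given as values. Other genes are named with a statement that they were chosen after their values were seen. Single values of 2 genes that the rule would name are not reported here.

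Transcript usage was planned with diffSpliceDGE of edgeR and a Simes p per gene, over 10418 genes. On counts simulated with no change in usage that test made 33 to 176 calls, depending on the contrast. A test with limma 3.58.1 on the arcsine square root of each transcript's share of its gene, with a Simes p per gene, was therefore added. It was picked out of 8 methods on simulated counts, where it made 0 to 3 calls with no change, before it was run on the deposited counts. It used 8795 genes with at least 10 counts in every library. Fisher's exact test, two-sided, compared calls among targets of ESRP proteins with calls among other genes, in 12 tests (6 contrasts by 2 usage tests) adjusted together.

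The edgeR gene test, camera and the usage tests were run on simulated counts with known changes, drawn from the real means, dispersions and library sizes. Fry, the replicate block and Fisher's exact test were not simulated. At a 2-fold change edgeR recovered 7% of 100 genes in the M6 contrast, 22% in M27H4, 4% in 3T3-L1, 0% for the difference between overexpression effects, 13% between lines and 0% for knockdown minus overexpression. At a 4-fold change it recovered 54%, 58%, 44%, 19%, 56% and 33% in the same order. A simulated list of 30 genes raised 1.5-fold was called by camera with the preset correlation in all 6 contrasts and with the estimated correlation in 5, missing knockdown minus overexpression. No unchanged simulated list was called. For the usage tests the 2 most abundant transcripts of 200 genes exchanged their levels. Depending on the contrast, diffSpliceDGE recovered 39 to 65% of these genes and made 64 to 234 false calls among 142 to 336 calls. The share test recovered 65.5 to 89.5% and made 10 to 16 false calls among 141 to 195 calls. Genes and transcripts were drawn independently of each other, so these counts could not show false calls that come from correlation between them.

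Replicate numbers were checked as pairs through the correlation of deviations from the group mean. Control and overexpression replicates with the same number correlated at 0.599, 0.34 and 0.356 in M27H4, so the numbers were taken as pairs there. The labels also give each M27H4 and 3T3-L1 pair shared sequencing lanes. The 3T3-L1 pairs correlated at 0.356, a single value, since with 2 replicates per group both pairs have the same correlation by construction. In M27H4 replicates 2 and 3 also correlated across numbers at 0.314 and 0.203. The main fit, as planned, left the pairs out, and they entered only as the replicate block among the alternatives. Leaving out positively correlated pairs can make p values too large. In M27H4 and 3T3-L1 358 and 201 genes reached an unadjusted edgeR p under 0.05, against 1062 by chance. A missing call in these lines is therefore no evidence of no response.

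The alternatives tried were DESeq2 1.42.0, limma voom, size factors of the DESeq2 kind, no filter, a filter at 10 counts, fits of only the lines compared, a replicate block, columns as libraries, technical replicate 1 alone, M6 technical replicates with different codes as separate libraries, and each replicate left out. A fit with only the M6 columns of the lane whose labelled samples were all M6 was planned for the genes of M6 knockdown. Added after seeing the data were such fits for the other results, the share test, and fits without genes counted all or none between lanes.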

Results

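The series measured RNA in 3 mouse cell lines in which the amount of Esrp2-as, a long noncoding RNA transcribed antisense to Esrp2, was changed. M6 and M27H4 are lines from mammary tumours of mice that carry the SV40 T antigen under the C3(1) promoter, and 3T3-L1 is a preadipocyte line. In M6 the RNA was knocked down with LNA antisense gapmers, in 2 replicates against 2 control replicates that the labels call an empty vector control. In M27H4 a transcript of Esrp2-as was overexpressed in 3 replicates against 3 controls, and in 3T3-L1 in 2 against 2. The 21 deposited columns held 34892461 to 138313667 counts each, and the 14 replicates made from them held 34892461 to 328493417. Between 15014 and 19971 genes had at least 10 counts in a replicate, and the 10 most abundant genes took 6.07 to 12% of the counts. Mitochondrially encoded genes took 0.135 to 0.591% and residual ribosomal and small structured RNA 2.27 to 5.38%. All M6 columns of replicate 1, and 1 column of each M6 replicate 2, came from a lane whose labelled samples were all M6, called the M6-only lane here. The signal column that matched no sample was also named for that lane, so it may have held a library of another line. The other columns of M6 replicate 2 came from lanes shared with the other lines. Every M27H4 and 3T3-L1 pair shared its lanes.

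The first question was whether Esrp2-as had changed as labelled and whether Esrp2, which encodes an epithelial splicing regulator, moved with it. Esrp2-as (1810019D21Rik, ENSMUSG00000086390) lies on chromosome 8 from 106135400 to 106138525 on the plus strand. Esrp2 (ENSMUSG00000084128) lies on the minus strand from 106130319 to 106136974, so 1575 bp of the genes overlap, and reads from the overlap make both values uncertain because the counting strand is not stated. The exons of transcript 203 of Esrp2-as (ENSMUST00000145343) lie outside this overlap, though the RefSeq end of Esrp2 at 106137193 reaches into the first of them. This transcript held 99.1 to 99.8% of the Esrp2-as counts in the overexpression columns and 91.1 to 100% in the M27H4 and 3T3-L1 control columns. In the M6 control columns it held 15.6 to 69.2%. Of the knockdown columns, both in the M6-only lane held 0% (0 of 25 and 0 of 50 counts) and the one in lane 20998 held 84.3% (86 of 102). Esrp2-as was 2.69 CPM ± 0.382 (SD, n = 2) in M6 control and 0.689 ± 0.229 (n = 2) in M6 knockdown. This was a log2 fold change of -1.92 (SE 0.55), with an interval at 95% from -3.10 to -0.73. Its edgeR adjusted p over all genes was 0.363, so it was no call, while DESeq2 gave an adjusted p of 0.0355 and edgeR with columns as libraries, which counts repeat runs of a culture as separate samples, 0.0139. Per column, over the column's own total, the knockdown held 0.566 and 0.644 CPM in the M6-only lane, where the controls held 3.21 and 2.68 CPM. In lane 20998, which also held an overexpression library of each other line and no M6 control, the knockdown held 0.939 CPM.

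Overexpression raised Esrp2-as in both other lines. In M27H4 it rose from 0.957 CPM ± 0.266 (SD, n = 3) to 47.7 ± 27.6 (n = 3), 49.1-fold, with an edgeR adjusted p of 0.00152. The 3 overexpression replicates held 61.2, 65.9 and 15.9 CPM. In 3T3-L1 it rose from 0.302 CPM ± 0.0742 (n = 2) to 40.6 ± 7.28 (n = 2), 135-fold, with an edgeR adjusted p of 0.00258. Every control column of both lines came from a lane that also held an overexpression library. Reads carried within a lane may therefore make up part of these control levels, and the sizes of both folds are uncertain. With the replicate pairs as a block the log2 changes were 5.40 and 7.09, and the adjusted p values were 0.0794 and 0.0823. The 3T3-L1 call also ended without control replicate 1 (adjusted p = 0.116) or control replicate 2 (0.223), and the M27H4 call ended in a fit of M27H4 alone (0.821).

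Esrp2 passed no test in any line. It was 62.4 CPM ± 5.02 (SD, n = 2) in M6 control and 54.8 ± 1.20 (n = 2) in knockdown, a log2 change of -0.19 with an interval at 95% from -0.69 to 0.32. In M27H4 it was 13.3 CPM ± 1.88 (n = 3) in control and 12.6 ± 3.30 (n = 3) in overexpression, with an interval from -0.49 to 0.34 around -0.07. In 3T3-L1 it was near the limit of what was measured, at 0.305 CPM ± 0.0198 (n = 2) and 0.338 ± 0.0255 (n = 2), with an interval from -0.43 to 0.73 around 0.15. All 3T3-L1 lanes also held M6 columns, with 52 to 55.5 CPM of Esrp2. Carried reads may therefore make up part or all of the 3T3-L1 level, which was not tested. All 3 edgeR adjusted p values were 1.

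**Figure D1:**
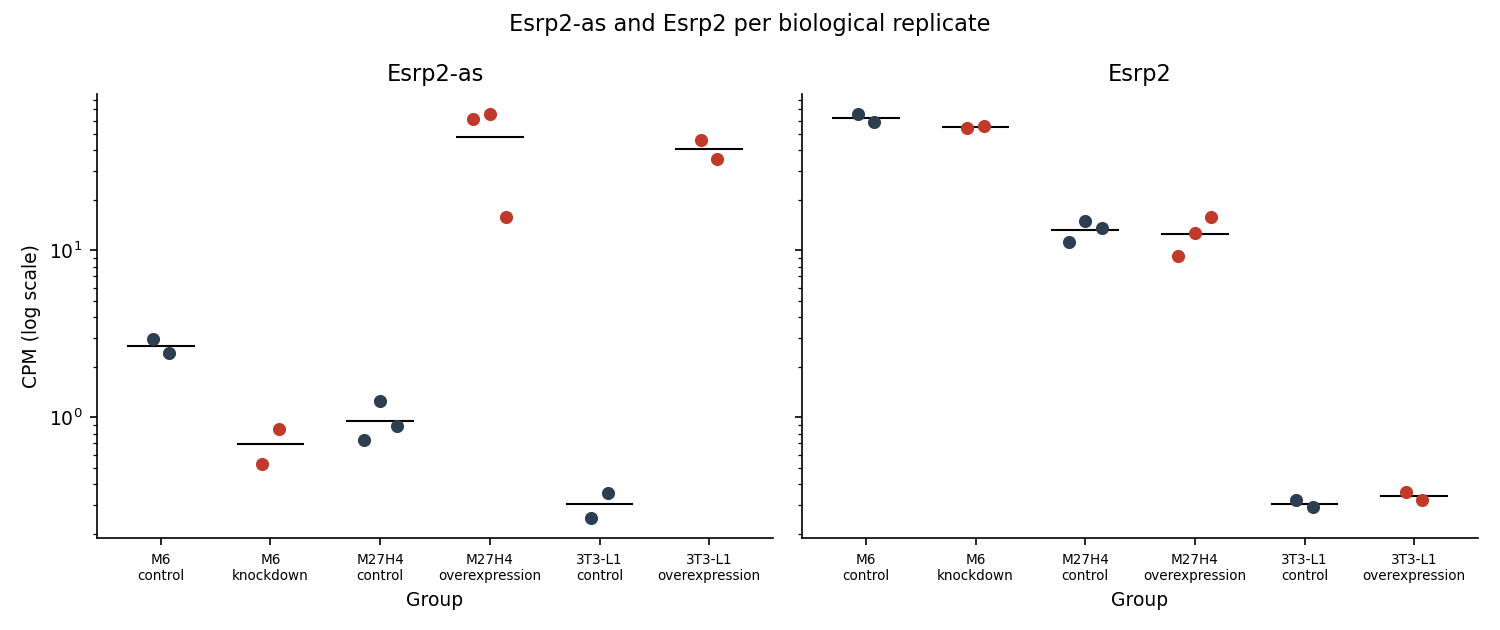
CPM of Esrp2-as and of Esrp2 per biological replicate in the 6 groups, on a log scale, with bars at the group means. Esrp2-as had a mean of 2.69 CPM in M6 control and 0.689 CPM in knockdown, with no adjusted edgeR call, and stood at 47.7 and 40.6 CPM in the overexpression groups, while Esrp2 means within a line differed by less.

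**Figure D2:**
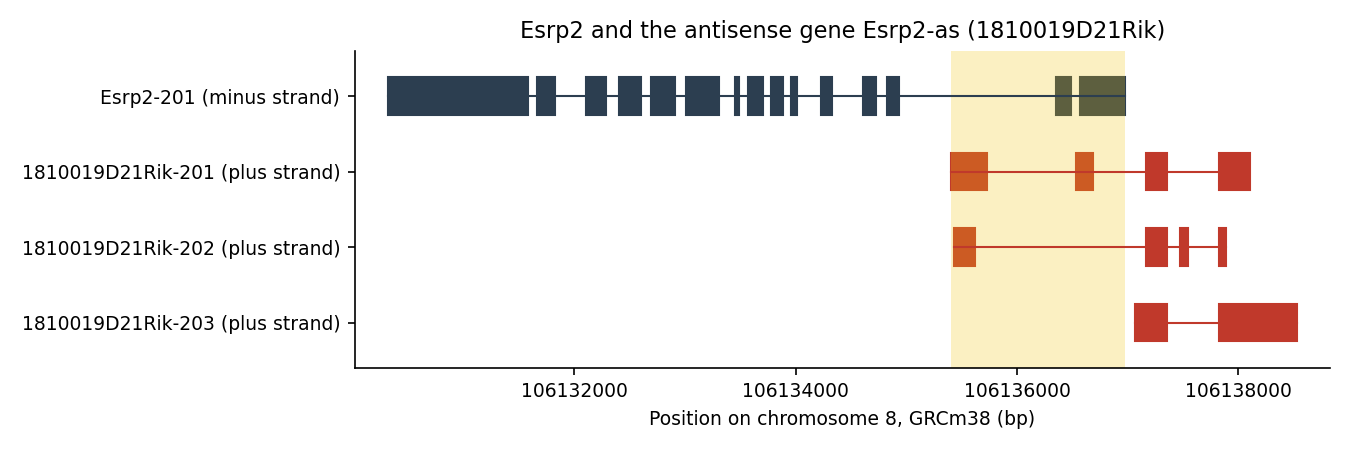
Exons of Esrp2-201 and of 3 Esrp2-as transcripts on chromosome 8 of GRCm38, with the position in bases on the x axis. The shaded overlap runs from 106135400 to 106136974, and the exons of transcript 203 of Esrp2-as, from 106137065 to 106137350 and from 106137828 to 106138525, lie outside it.

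In M6 the question was which genes moved when Esrp2-as was knocked down. S100a7a (ENSMUSG00000063767, chromosome 3 from 90654017 to 90658669), which encodes a small calcium-binding protein of the S100 family, rose 15.8-fold, from 0.355 CPM ± 0.0840 (SD, n = 2) to 5.47 ± 0.863 (n = 2). Ccng1, the p53 target cyclin G1, rose from 94.5 CPM ± 12.3 (n = 2) to 399.5 ± 19.1 (n = 2), a log2 change of 2.08 (SE 0.21). Eda2r, a receptor of the tumour necrosis factor family and a p53 target, rose from 2.60 CPM ± 0.339 (n = 2) to 18.0 ± 0.517 (n = 2). Fst, which encodes the activin-binding protein follistatin, rose from 6.09 CPM ± 1.87 (n = 2) to 29.2 ± 2.91 (n = 2). Fam189a2 fell from 13.6 CPM ± 6.52 (n = 2) to 1.39 ± 0.201 (n = 2).

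By edgeR 29 of 21237 genes were called, 26 higher and 3 lower, and 1331 had an unadjusted p under 0.05 where 1062 would by chance alone. S100a7a and Ccng1 had an adjusted p of 0.00144, Fst 0.00221, Eda2r 0.00479 and Fam189a2 0.0343. The other largest rises were in Cd80, a costimulatory ligand of T cells, at a log2 change of 4.32 (adjusted p = 0.0478), and in Slc7a11, the cystine transporter, at 2.92 (0.0217). The size of the Cd80 change is uncertain, as the controls held 0 and 0.146 CPM and without control replicate 2 it was a fold over a group at 0, and Slc7a11 was at 2.17 without knockdown replicate 1. On the log2 scale Zfp365 rose by 2.50 (adjusted p = 0.0125), Itga2, the collagen-binding integrin subunit alpha 2, by 2.46 (0.0274) and Styk1 by 2.19 (0.0167). Adamtsl3 fell, with a log2 change of -1.75 (adjusted p = 0.0478). The number of calls rested on the setting: it was 233 by DESeq2, 64 by limma voom, 41 with only the columns of the M6-only lane (24 of them shared with the 29) and 0 with only the M6 libraries in the fit. It was 6 without control replicate 1, 60 without control replicate 2, 11 without knockdown replicate 1 and 47 without knockdown replicate 2. Of the genes named in this paragraph and the one before, S100a7a, Ccng1 and Fst kept their call with every replicate left out, and each of the others lost it at least once.

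Targets of p53 stood higher as a group in the knockdown: 24 of 30 had a positive log2 change, with a median of 0.52 (camera adjusted p = 1.66e-15, and adjusted p = 0.00757 with an estimated correlation). Eda2r and Ccng1 rose over all genes tested, and 7 members rose when adjusted over the list alone. Among these, Cdkn1a, the cell cycle inhibitor p21, had a log2 change of 2.10 (adjusted p over all genes = 0.117), Zmat3 1.21 (0.106) and Sesn2, a stress-induced regulator of mTORC1, 0.99 (0.216). The list was called by camera in every fit, but with an estimated correlation its adjusted p was 0.177 without control replicate 2, 0.0657 without knockdown replicate 2 and 0.554 with only the M6 libraries. With only the columns of the M6-only lane it was 0.0218.

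**Figure D3:**
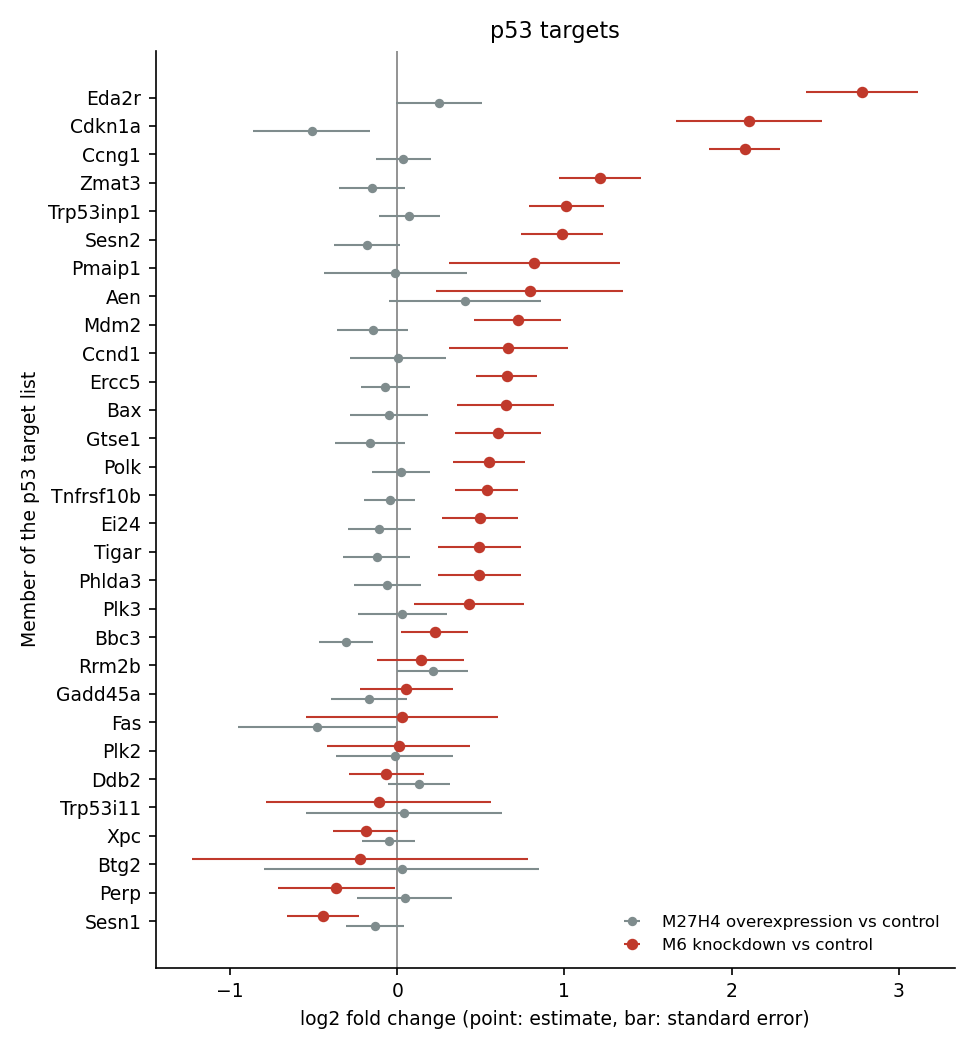
Log2 fold change with its standard error for 30 p53 targets in M6 knockdown against control and in M27H4 overexpression against control. Eda2r, Cdkn1a and Ccng1 stand highest in M6 at 2.78, 2.10 and 2.08, and none of the 30 was called in M27H4.

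Camera with the preset correlation called 9 more lists in M6, and none of these was called with an estimated correlation. Interferon response genes leaned lower in 43 of 45 members, with a median of -0.41 (adjusted p = 4.25e-07, and 0.554 with an estimated correlation). No member was called, and the smallest p values belonged to Rtp4 at a log2 change of -1.42, Isg15 at -0.79, Oasl2 at -0.68 and Oas1b at -0.68. These values rested on control replicate 1, and without it they were -0.29, -0.07, -0.02 and -0.05, and the list was not called (camera adjusted p = 0.61). Genes of NF-kB and inflammatory cytokines leaned higher in 29 of 33 members (adjusted p = 0.000121, and 0.554 with an estimated correlation), with Csf2 at 5.06 (gene adjusted p = 0.207), Ptgs2 at 2.23, Csf3 at 1.97 and Lif at 1.52, and 1 member called when adjusted over the list alone. Ptgs2 held 232.1 and 95.9 CPM in the controls and 998.3 and 537.9 CPM in the knockdown, so the size of its change varied with the replicate. Without knockdown replicate 1 (Csf2 at 7.74 CPM, against 0.913 CPM in replicate 2) Csf2 was at 2.83 and Lif at 0.94, and without control replicate 2 the list was not called (0.12). In the mesenchymal list 16 of 30 members were higher (adjusted p = 0.01, and 0.141 with an estimated correlation). Zeb1, a repressor of epithelial genes, rose from 1.66 CPM ± 0.325 (SD, n = 2) to 5.53 ± 1.19 (n = 2), with an edgeR adjusted p of 0.0125. Snai2, Mmp3 and Zeb2 were at log2 changes of 1.67, 1.02 and 0.92 with no call over all genes (Snai2 at 0.96 without knockdown replicate 1), and 3 members of the list were called when adjusted over the list alone.

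Genes of G1/S and DNA replication leaned lower in 37 of 40 members (adjusted p = 0.000241, and 0.856 with an estimated correlation), with Rfc4 at a log2 change of -0.77, Rfc3 at -0.44, Prim1 at -0.44 and Gins2 at -0.39. Replication-dependent histones leaned lower in 34 of 35 (0.000603, and 0.856 with an estimated correlation), among them Hist4h4 at -0.66. All 52 genes of cytosolic ribosomal proteins were lower (0.0201, and 0.913 with an estimated correlation), with Rpl22 at -0.74 and Rps4x at -0.36. Genes of cholesterol and fatty acid synthesis were higher in 25 of 33 members (0.0201, and 0.856 with an estimated correlation), with Hsd17b7 at 0.62. Heat shock and oxidative stress genes were higher in 14 of 23 (0.0201, and 0.554 with an estimated correlation), with Hsph1 at 0.64 and Nqo1 at 0.51. The unfolded protein and integrated stress response leaned higher in 23 of 35 (0.0201, and 0.856 with an estimated correlation), with Manf at 0.70 and Atf3 at -1.50. In the M6-only lane the ribosomal list turned its direction (adjusted p = 0.982), and the cholesterol list (0.164) and the histones (0.33) were not called. In a fit of only the M6 libraries the ribosomal (0.0555) and heat shock (0.0672) lists were not called. Without control replicate 2 Hist4h4 turned to 0.22 and Rps4x to 0.14, Rfc3 was at -0.04 and Gins2 at -0.16, and the histones (0.337), the G1/S (0.0542) and the mesenchymal (0.0807) lists were not called, while the ribosomal list was called higher (0.000493, and 0.79 with an estimated correlation). Without control replicate 1, which held 29.4 CPM of Atf3 against 4.33 CPM in replicate 2, Atf3 turned to 0.53, Manf was at 0.34 and Nqo1 at 0.25, and the cholesterol (0.367), heat shock (0.12) and unfolded protein (0.0864) lists were not called. Over all 4 replicates left out in turn, only the p53 list kept its camera call throughout.

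The other 19 lists were not called in M6. Camera adjusted p values were 0.11 for Esrp2 neighbours on chromosome 8, 0.163 for G2/M and mitosis, 0.164 for preadipocyte and fibroblast genes, 0.236 for ESRP-regulated splicing targets, 0.334 for Wnt and beta-catenin targets and 0.379 for epithelial identity. They were 0.556 for basal and myoepithelial genes, 0.615 each for endothelial cells, immune cells, hypoxia and glycolysis, and extracellular matrix and collagens, 0.634 for immediate early genes and 0.644 for nuclear-retained lncRNA. They were 0.749 for TGF-beta and SMAD targets, whose median of -0.04 went against an upward test, 0.814 for luminal mammary genes, 0.824 for mitochondrially encoded genes, 0.908 each for adipocyte differentiation and residual ribosomal RNA, and 0.951 for splicing regulators.

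Transcript shares were compared in M6 because ESRP proteins regulate splicing. Limma on shares called 2 of 8795 genes, with 447 at an unadjusted p under 0.05 and 440 expected by chance. Both were named after their values were seen. Ubl4a-207 rose to 25.8% ± 0.629 (SD, n = 2) of its gene, with an adjusted p of 2.57e-07. In control it held 0 of 6867 counts (n = 2), which by counting error alone allows a share of up to 0.0437%. Slc2a9-201 fell from 8.14% ± 0.992 (n = 2) to 0.142% ± 0.2 (n = 2), with 0.00306. None of 27 ESRP targets was called over all genes, and 2 were called when adjusted over the list alone. For Cd44, a hyaluronan receptor whose variable exons are spliced by ESRP proteins, Cd44-201 was at 14.8% ± 0.0346 (n = 2) in control and 2.45% ± 0.394 (n = 2) in knockdown (adjusted p over the list alone = 0.00812, over all genes 0.335), and diffSpliceDGE gave Cd44 an adjusted p of 1. For Fgfr2 the share of Fgfr2-211 was 28.7% ± 6.09 (n = 2) in control and 1.63% ± 2.30 (n = 2) in knockdown (0.00393 over the list alone), but over the M6 control columns it ran from 0 to 81.1%. The planned diffSpliceDGE test called 20 of 10418 genes against 33 on counts simulated with no change. In the deposited counts 2995 transcripts were at 0 in 1 lane and at 100 counts or more in the other lane of the same library, so a count of 0 sets no firm limit on a share. With only the columns of the M6-only lane the share test called 45 of 8772 genes, of which 1 was shared with the fit of all columns. On counts simulated with no change it made 2 calls there. In that lane 859 genes had an unadjusted p under 0.05, and of 27 ESRP targets 0 were called over all genes and 3 over the list alone.

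**Figure D4:**
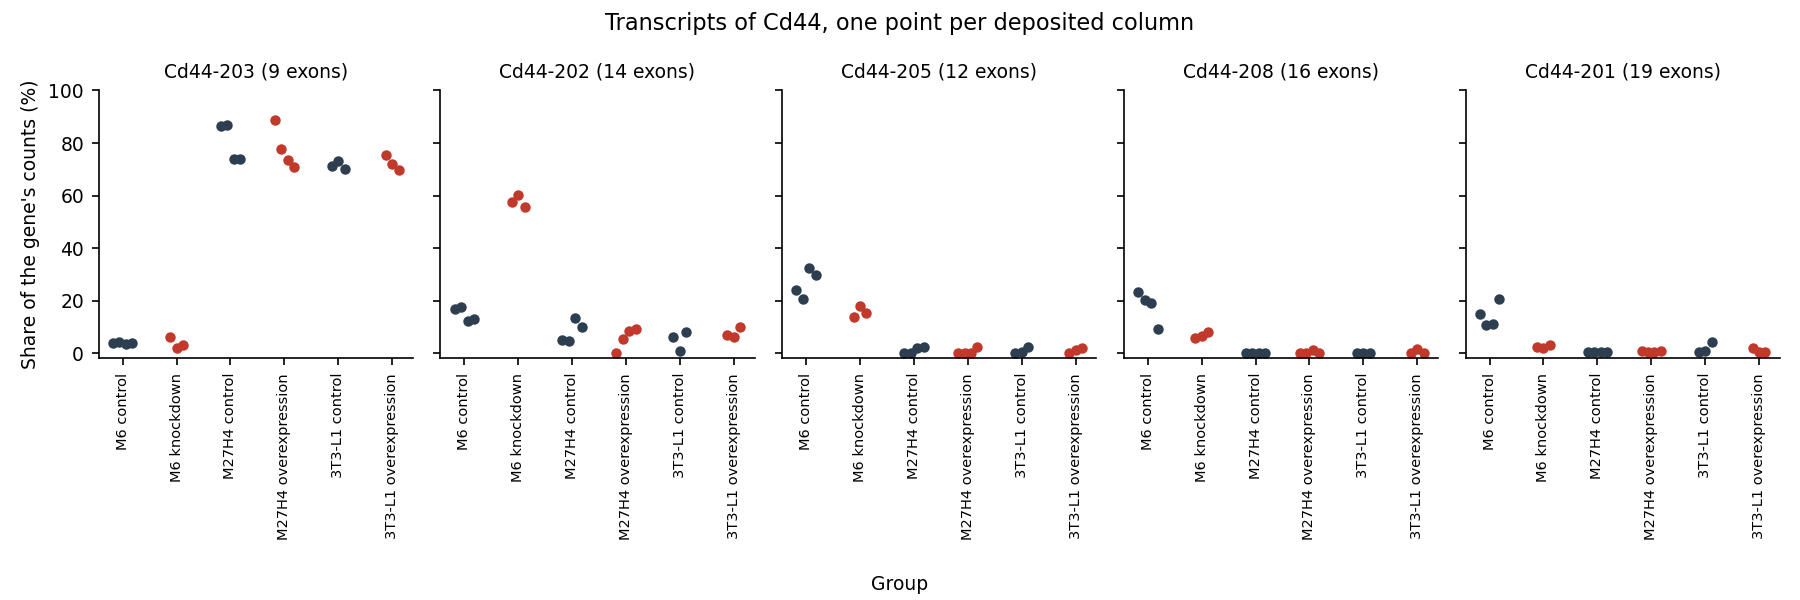
Share of Cd44 counts in 5 of its transcripts, in percent, per deposited column in the 6 groups. The share of Cd44-202, chosen after its values were seen, lay between 12.4 and 17.5% in the M6 control columns and between 55.6 and 60.1% in the knockdown columns, and Cd44-203 averaged 80.1% in M27H4 control.

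In M27H4 the question was which genes moved when Esrp2-as was overexpressed. Apart from Esrp2-as itself, edgeR called 1 feature out of 21237, ENSMUSG00000107554, which has no entry in GENCODE M21 (adjusted p = 0.00666) and was named after its values were seen. It stood at 4.70 CPM ± 0.974 (SD, n = 3) in control and at 0 counts in all 3 overexpression libraries, at least 619-fold lower against a floor of 3 counts over the group, but in 1 control library it held 851 counts in lane 20283 and 0 in lane 20282. Pou2f1, which encodes the transcription factor Oct-1, had the next smallest p at 10.3 CPM ± 3.95 (SD, n = 3) in control and 3.53 ± 0.8 (n = 3) in overexpression, with an edgeR adjusted p of 0.812. Fam102b stood at a log2 change of -1.03, Ifi27l2a at 0.91 and Elmo2 at -0.52, also without a call. An unadjusted p under 0.05 was reached by 358 genes where 1062 would by chance alone, and DESeq2 called 6 genes and limma voom 1.

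Interferon response genes leaned higher in M27H4 overexpression, in 40 of 45 members with a median of 0.34 (camera adjusted p = 9.6e-12, and 0.275 with an estimated correlation). No member was called, with Oas1a at a log2 change of 0.92, Xaf1 at 0.79, Ifit3b at 0.68 and Ifi27 at 0.52. Nuclear-retained lncRNA leaned higher in 14 of 16 (0.000129, and 0.275 with an estimated correlation), with Malat1 at 2.19 (50.3, 93.4 and 478.9 CPM in the overexpression replicates, and 0.65 without replicate 3), Dleu2 at 1.02 (0.39 without overexpression replicate 2) and Snhg1 at 0.36. The size of the Malat1 change is uncertain, as its counts could differ widely between lanes 20282 and 20283 of the same library. They were 10007 and 60097 in 3T3-L1 control replicate 1, but 9352 and 12884 in M27H4 overexpression replicate 2 and 2914 and 4838 in M27H4 control replicate 2. Hypoxia and glycolysis genes leaned lower in 30 of 36 (0.000342, and 0.598 with an estimated correlation), with Gapdh at -0.52, Gpi1 at -0.42, Egln1, an oxygen-sensing prolyl hydroxylase, at -0.40 and Hk1 at -0.35. Without control replicate 1 Gapdh was at -0.08 and Egln1 at -0.21, and the list was not called (0.9). Cholesterol and fatty acid synthesis genes leaned lower in 30 of 33 (0.00748, and 0.598 with an estimated correlation), with Me1 at -0.50 (-0.25 without overexpression replicate 1), Fasn at -0.36 (-0.21 without control replicate 1) and Scd2 at -0.31. ESRP-regulated splicing targets leaned lower as genes in 26 of 29 (0.00748, and 0.598 with an estimated correlation), with Fgfr1 at -0.29 and Ctnnd1, p120 catenin, at -0.27.

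Genes of NF-kB and inflammatory cytokines leaned lower in 26 of 33 members (0.0179, and 0.598 with an estimated correlation), with Cxcl5 at -1.79 and Sod2 at -0.62. Both values rested on control replicate 1 (446.2 and 209.7 CPM against at most 45.1 and 81.9 CPM in the other controls), and without it they were 0.47 and 0.001, and the list was called higher instead (0.00546, and 0.526 with an estimated correlation). Replication-dependent histones leaned lower in 31 of 35 (0.0327, and 0.887 with an estimated correlation), with a median of -0.17 and a mean of 0.04. With the replicate pairs as a block, extracellular matrix genes (adjusted p = 0.00354, without the block 0.0529) and TGF-beta targets (0.0439, without it 0.222) were called lower too, with adjusted p values of 0.647 and 0.652 with an estimated correlation. The number of lists called was 2 without overexpression replicate 2 and 12 without control replicate 3, against 7, and only the interferon list kept its camera call with every replicate left out. No list was called with an estimated correlation or by fry. The share test called 0 of 8795 genes, with 297 at an unadjusted p under 0.05, while diffSpliceDGE called 151 of 10418 against 111 on counts simulated with no change, with 2 of 28 ESRP targets among them (two-sided Fisher exact adjusted p = 0.148).

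In 3T3-L1, which expressed little Esrp2, the question was whether overexpression of Esrp2-as moved genes in a line of another kind. Only Esrp2-as itself was called by edgeR, with 201 genes at an unadjusted p under 0.05 where 1062 would be by chance, and DESeq2 called 12 and limma voom 3. Ldlrad3 stood at 48.6 CPM ± 3.82 (SD, n = 2) in overexpression and 13.2 ± 2.08 (n = 2) in control, with an edgeR adjusted p of 0.249. Pcdhgc3, a protocadherin, stood at 90.5 CPM ± 37.5 (n = 2) and 17.6 ± 2.17 (n = 2), with an adjusted p of 0.39, and Mir17hg and Tmem86b had log2 changes of -3.40 (-1.91 without control replicate 1) and -1.73. No list was called by camera with either correlation or by fry. The smallest adjusted p, 0.111, belonged to the replication-dependent histones, of which 34 of 35 were higher. Leaving out any replicate gave 3 to 4 list calls by the preset correlation, none of them kept with an estimated correlation (adjusted p from 0.938 to 0.991). Among them G1/S genes were called higher without control replicate 1 (adjusted p = 1.05e-06) or overexpression replicate 2 (2.33e-05) and lower without control replicate 2 (1.92e-11) or overexpression replicate 1 (3.19e-07), and G2/M genes turned in the same way.

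In the epithelial list of 3T3-L1 Spint1, an inhibitor of serine proteases, had a log2 change of 0.57 and was not called. It stood at 0.360 to 0.595 CPM in the 3T3-L1 replicates and at 108.4 to 134.7 CPM in M6, and all 3T3-L1 lanes also held M6 libraries. Reads carried from M6 may make up such levels of epithelial genes in 3T3-L1, which was not tested. With the replicate pairs as a block camera called 3 lists higher, the histones (adjusted p = 0.00435), epithelial identity (0.0179) and extracellular matrix (0.0179), each with an adjusted p of 0.88 with an estimated correlation, and edgeR called 0 genes. The number of genes called was 0 without control replicate 2, 2 without control replicate 1 and 5 without overexpression replicate 1. The share test called 17 of 8795 genes, 1 with the block. Among the 17 was Fgfr2-210, at 1.81% ± 0.474 (SD, n = 2) in overexpression and 0 of 9923 counts in control (n = 2), with an adjusted p of 0.0309. By counting error alone this 0 allows a share of up to 0.0302%, but it sets no firm limit if reads were assigned to other transcripts. The diffSpliceDGE test called 41 genes against 39 on counts simulated with no change. Among them were 3 of 28 ESRP targets against 38 of 10390 other genes (two-sided Fisher exact adjusted p = 0.00104), while the share test had 1 of 27 against 16 of 8768 (0.148). In 2 of these 3 targets, named after their values were seen, the transcript with the smallest p was counted in a single library, Enah-203 at 33.2% ± 46.9 (n = 2) in control and Sec31a-210 at 1.63% ± 2.30 (n = 2) in overexpression, so the enrichment rested on them.

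The overexpression effect in M27H4 was then set against that in 3T3-L1. The effect on Esrp2-as differed by a log2 value of -1.46 with an interval at 95% from -2.95 to 0.02, so a difference was not called. Esrp2-as was the 1 gene called in both lines. As it was overexpressed in both by design, this overlap shows no shared response of other genes. Across 13508 genes of at least 1 CPM the log2 changes of the lines correlated at -0.05 (Pearson) and -0.30 (Spearman), where genes are not independent replicates. The test of the difference called 1 feature, ENSMUSG00000107554 (adjusted p = 0.0277), with 320 genes at an unadjusted p under 0.05, 11 calls by DESeq2 and 0 by limma voom. Pcdhgc3 and Ldlrad3 had differences of -2.84 (adjusted p = 0.864) and -1.97 (0.987).

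Camera called 7 lists in this difference, of which none was called with an estimated correlation or by fry. Interferon genes (adjusted p = 1.44e-07, and 0.5 with an estimated correlation) and nuclear-retained lncRNA (0.00513, and 0.5) were higher in M27H4 overexpression relative to 3T3-L1. The histones (0.00394, and 0.844), ESRP targets (0.00513, and 0.683), cholesterol synthesis (0.0058, and 0.648), hypoxia and glycolysis (0.00614, and 0.771) and extracellular matrix (0.0435, and 0.5) were lower, where the values after each comma are adjusted p with an estimated correlation. Malat1, of the lncRNA list, held 10007 counts in lane 20282 and 60097 in lane 20283 of the library of 3T3-L1 control replicate 1. Its level there is therefore uncertain. Only the interferon list kept its camera call with every replicate left out. The lncRNA list was not called without 3T3-L1 control replicate 1 (0.171), and without control replicate 2 the histones (0.16), ESRP targets (0.201), hypoxia (0.0759) and extracellular matrix (0.158) lists were not. The block added basal genes (0.0314) and TGF-beta targets (0.0168), both with an adjusted p of 0.483 with an estimated correlation, and left 0 genes called. The share test called Klrg2 and Awat2 (1 gene with the block), named after their values were seen, and diffSpliceDGE called 106 genes against 173 on counts simulated with no change, with 3 of 28 ESRP targets among them (two-sided Fisher exact adjusted p = 0.0112), Sec31a included, against 0 of 27 by shares.

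The control groups of M6 and M27H4 were compared to describe the lines in which Esrp2-as was lowered and raised. All 35 measured genes of epithelial identity were called lower in M27H4 and 15 of 24 fibroblast genes higher, though camera gave these lists adjusted p values of 0.131 and 0.105 with an estimated correlation. Spint1 stood at 4.12 CPM ± 1.02 (SD, n = 3) in M27H4 and 125.6 ± 12.9 (n = 2) in M6, and Zeb2, a repressor of epithelial genes, at 136.3 ± 20 (n = 3) and 4.39 ± 1.11 (n = 2). Esrp2 was lower in M27H4 by edgeR (log2 change -2.23, adjusted p = 3.89e-06), and Esrp2-as at -1.47 had an adjusted p of 0.0321. The Esrp2-as call ended with limma voom (0.203), with no filter (0.0772), without M27H4 control replicate 1 (0.0851) or 3 (0.09) and without M6 control replicate 1 (0.148) or 2 (0.087).

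EdgeR called 6420 genes between the lines, 3236 higher and 3184 lower in M27H4. Within lanes 20282 and 20283, which held 1 control column of each line, 6361 (99.1%) and 6391 (99.5%) of them had the direction of the pooled value, to which these columns themselves contributed. The epithelial list had a camera adjusted p of 9.19e-33, and 0.131 with an estimated correlation, with Tjp3, a tight junction protein, at a log2 change of -5.69 and Elf3 at -5.67. Basal and myoepithelial genes were lower in 14 and higher in 4 of 23 (6.93e-06, and 0.266 with an estimated correlation), with Lamb3, a laminin chain, at -6.47, Jag2, a Notch ligand, at -4.96, Egfr at -3.73 and Krt16 at -3.48. Luminal mammary genes were lower in 10 and higher in 4 of 21 (0.0234, and 0.383 with an estimated correlation), with Aldh1a3 at -7.40 and Erbb3 at -4.37 but Areg, the EGF receptor ligand amphiregulin, at 2.32. Genes of NF-kB and inflammatory cytokines were lower in 11 and higher in 1 of 33 (5e-04, and 0.383 with an estimated correlation), with Tnf at -7.58, Ccl20 at -6.10 and Icam1 at -1.98.

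Preadipocyte and fibroblast genes were higher in M27H4 in 15 and lower in 2 of 24 (7.51e-07, and 0.105 with an estimated correlation), with Pdgfra, a growth factor receptor of mesenchymal cells, at 5.71, Sfrp1 at 9.29 and Col14a1 at 8.72. The mesenchymal list was higher in 11 and lower in 8 of 30 (0.0242, and 0.16 with an estimated correlation), with Ncam1 at 8.81, Axl at 2.66 and Zeb1 at 2.53. Extracellular matrix genes were higher in 17 and lower in 5 of 45 (0.0338, and 0.16 with an estimated correlation), with Lox, which crosslinks collagen, at 6.65, Sparc at 2.49 and Col18a1 at -3.37. In M6 control replicates 1 and 2 Ncam1 stood at 0.393 and 1.55 CPM, and Lox at 1.30 and 3.34 CPM. Replicate 2 came in part from lanes shared with M27H4 and 3T3-L1, so the sizes of these 2 changes are uncertain. Wnt targets were higher in 13 and lower in 5 of 23 (0.00473, and 0.239 with an estimated correlation), with Axin2 and Notum, feedback inhibitors of the pathway, at 7.41 and 6.13. The unfolded protein and integrated stress response was higher in 17 and lower in 5 of 35 (0.0123, and 0.467 with an estimated correlation), with Aldh1l2 at 3.94, Asns at 2.59 and Nupr1 at -2.49. Without M6 control replicate 1 the luminal list was not called (0.0505), nor was the extracellular matrix list without M6 control replicate 2 (0.0548). Fry called 15 lists.

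Of the largest single changes, several genes had no count in M6 control. Against a floor of 3 counts over the group, Chst8 was at least 919-fold higher in M27H4, C4bp at least 815-fold, Grk3 at least 708-fold and Hoxb7 at least 258-fold. Hpgd, which degrades prostaglandins, was at least 280-fold lower and Msc at least 262-fold lower. These bounds cover counting error alone and use group means, and the replicates differed. In the deposited counts 61 genes were at 0 in 1 lane and at 100 or more in the other lane of the same library. A count of 0 therefore sets no firm limit on these folds. Hpgd stood at 3.23 and 1.25 CPM in the M6 controls, and C4bp at 5.15, 3.11 and 12.3 CPM in the M27H4 controls. Transcript shares differed too, in 107 of 8795 genes by limma on shares and 208 of 10418 by diffSpliceDGE, against 0 and 62 on counts simulated with no change. The share test called 6 of 27 targets of ESRP proteins against 101 of 8768 other genes (two-sided Fisher exact p = 6.77e-07, adjusted 8.13e-06), while the planned diffSpliceDGE test called 2 of 28 against 206 of 10390 (p = 0.107, adjusted 0.214). Cd44-203, which has 9 exons, made up 80.1% ± 6.19 (SD, n = 3) of Cd44 in M27H4 and 3.87% ± 0.196 (n = 2) in M6, with an adjusted p of 0.00105. Epb41l5-202 made up 51.5% ± 4.55 (n = 3) and 2.44% ± 0.205 (n = 2), with 0.00038, and Slk, Arhgef10l, Mbnl1 and Fgfr2 were called as well.

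The effect of lowering Esrp2-as in M6 was last set against the effect of raising it in M27H4, to look for genes that moved in opposite directions. No gene was called in both comparisons in either direction by edgeR, with 0.00137 expected for independent lists, 1331 and 358 genes at an unadjusted p under 0.05 and 2 genes called in opposite directions by DESeq2. The log2 changes correlated across 13508 genes at -0.02 (Pearson) and -0.04 (Spearman), where genes are not independent replicates. The difference of the effects was called for 6 genes. Esrp2-as was at -7.53 (adjusted p = 0.00534), S100a7a at 3.83 (0.0115), Ccng1 at 2.04 (0.0167) and Fst at 2.36 (0.0178). Abcb1b, a drug efflux transporter at 2.19 (0.0178), and Gm26083, a small Cajal body RNA at -6.39 (0.00645), were chosen after their values were seen. The count was 0 without M6 knockdown replicate 1 and 26 without knockdown replicate 2, and it was 89 by DESeq2. The Esrp2-as call ended with limma voom (0.113) and without M6 knockdown replicate 1 (0.0561).

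P53 targets differed between the effects with either correlation (camera adjusted p = 3.22e-13, and 0.0129 with an estimated correlation) and by fry (0.00641). The call with an estimated correlation ended with only the lines compared (0.0805) and without M6 control replicate 2 (0.175), knockdown replicate 1 (0.0748) or knockdown replicate 2 (0.0702). Interferon genes had a lower effect in M6 in 45 of 45 members (6.12e-16, and 0.151 with an estimated correlation). Camera with the preset correlation called 11 more lists, none of which was called with an estimated correlation. Higher in M6 were NF-kB and inflammatory cytokines (9.76e-07, and 0.301 with an estimated correlation), cholesterol synthesis (0.000571, and 0.334), heat shock (0.00424, and 0.301), the mesenchymal list (0.00483, and 0.0974), the unfolded protein response (0.00667, and 0.526), ESRP targets (0.00851, and 0.65), Esrp2 neighbours (0.0278, and 0.705) and preadipocyte genes (0.0417, and 0.622). Lower were ribosomal proteins (0.00674, and 0.934), nuclear-retained lncRNA (0.0106, and 0.311) and G1/S genes (0.0107, and 0.934). With only the columns of the M6-only lane ESRP targets (0.104), Esrp2 neighbours (0.0698), ribosomal proteins (0.501) and nuclear-retained lncRNA (0.0885) were not called. These 4 lists, G1/S genes, NF-kB genes and preadipocyte genes each lost their camera call in at least 1 fit with a replicate left out. The share test called 2 genes, Ubl4a and Slc2a9, and diffSpliceDGE 133 against 176 on counts simulated with no change.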

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

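The tests of carry-over between lanes, of the explanations for the p53 targets and of other splits of the samples were chosen only after the result was seen, while those on transcript reassignment and on lane differences were not. A difference between the overexpression effects of M27H4 and 3T3-L1, tested directly, singled out 8 results. For ENSMUSG00000107554 the effect in M27H4 minus that in 3T3-L1 was -14.23 on the log2 scale, a fitted value that depends on the handling of groups at 0. For the other 7 results, all gene lists, the camera adjusted p of the difference was 1.44e-07 for interferon response, 0.00394 for replication-dependent histones, 0.00513 for ESRP-regulated splicing targets and 0.00513 for nuclear-retained lncRNA. It was 0.0058 for cholesterol and fatty acid synthesis, 0.00614 for hypoxia and glycolysis and 0.0435 for extracellular matrix and collagens, and none of the 7 was called with an estimated correlation. Only the interferon list kept its call with every replicate left out, and nuclear-retained lncRNA, for example, was at 0.171 without 3T3-L1 control replicate 1.

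The first pattern is that transcripts abundant in 3T3-L1 appeared in M6 and M27H4 columns from lanes shared with 3T3-L1. Over 19 genes above 200 CPM in 3T3-L1 and under 1 CPM in M27H4 columns of a lane with M27H4 alone, the median in M6 was 0.211 CPM in the M6-only lane and 3.51 CPM in shared lanes. This excess came to a median of 0.555% of the 3T3-L1 level in M6 and 0.969% in M27H4 over 25 genes chosen in the same way on the M6-only lane, so reads or RNA carried between libraries of a lane may account for it. In M27H4 the lane with M27H4 alone held only replicate 1, and the shared lanes held only replicates 2 and 3. A difference between cultures therefore cannot be told apart from carry-over in M27H4. Cells of 3T3-L1 in the M6 cultures of replicate 2 are argued against, since the columns of that replicate in the M6-only lane showed a median excess of 0% (quartiles -0.573 and 0.0103), which holds only if its columns, labelled technical replicates but with different library codes, came from the same cultures. No biological explanation was tested, and the Esrp2-as counts of M6 knockdown in lane 20998 and of M6 control in lanes 20282 and 20283, which all held overexpression libraries of both other lines, stand under the same doubt. So do those of every M27H4 and 3T3-L1 control column, whose lanes held overexpression columns at 15.6 to 68.1 CPM of Esrp2-as. The folds of overexpression and the Esrp2-as difference between the M27H4 and M6 controls rest on these counts.

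The next pattern is that 61 genes and 2995 transcripts were at 0 in 1 lane and at 100 counts or more in the other lane of the same library. These numbers leave out genes that differed widely between lanes without reaching 0. Malat1, for example, held 10007 and 60097 counts in lanes 20282 and 20283 of 3T3-L1 control replicate 1, and 2701 and 13587 in those of M6 control replicate 2. The fits without genes counted all or none kept such genes. A difference between the lanes stays open as a cause. In a fit of lane with the library as a block edgeR called 2 genes, and only 1 of them was among the 61. That fit looks for the same change in every library, so it may miss a gene that changed in 1 library only. ENSMUSG00000107554 was at 0 in lane 20282 in M27H4 control replicate 2 and in 3T3-L1 control and overexpression replicate 1. In lane 20283 these libraries held 851, 474 and 616 counts of it. H1fx went the other way in M27H4 control replicate 2, with 135 counts in lane 20282 and 0 in lane 20283. For the transcripts, a candidate explanation is that the deposited counting assigned the reads of a gene to another of its transcripts. The CPM of the whole gene differed between lanes by a median of 0.0853 on the log2 scale, where the median over all genes was 0.063. This does not decide between reassigned and lost reads. The transcript's share of its gene was not taken into account, and losing a minor transcript would also leave the gene nearly level. ENSMUSG00000107554 and Fgfr2-211 showed such zeros, for whole genes such as the former the cause stays open, and no biological explanation was tested.

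The last pattern is the higher p53 targets in M6 knockdown, in cells whose tumours were driven by SV40 large T antigen, a protein that binds p53. Different lanes and library codes of replicate 2 are argued against as the whole cause, since with only the M6-only lane the list kept an adjusted p of 0.0218 with an estimated correlation. Size factors of the DESeq2 kind gave 0.00563, which decides nothing about normalisation because they shifted the genes almost alike (SD of the shift 0.026 on the log2 scale), and over all fits that p ran up to 0.554 with only the M6 libraries. An effect of the gapmer treatment itself cannot be told apart from an effect of less Esrp2-as, because no group is labelled as given a gapmer without a target, the M6 control being labelled an empty vector control, and the list's adjusted p of 0.499 in M27H4 overexpression comes from a line without gapmers. That lower Esrp2-as may raise p53 targets therefore stays an untested hypothesis beside it.

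For M27H4, 3 samples against 3 make 10 splits, too few for a share under 0.05. The real split gave 2 genes, a number reached by 4 of the 10 splits counting the real one, with 5 in the highest other. It gave 7 lists by camera, a number reached by 6 of the 10 splits, with 10 in the highest other. It gave 151 genes by diffSpliceDGE, a number reached by 7 of the 10 splits, with 332 in the highest other. The 4 splits that put both replicate 1 libraries, which shared lane 20284, in the same group gave 0, 3, 5 and 2 genes, 7, 10, 10 and 9 lists and 182, 315, 173 and 332 genes by diffSpliceDGE, and the 5 other splits gave 122 to 207 by diffSpliceDGE. Splits that part all 3 pairs, as the real one does, gave 0, 0 and 0 genes, 5, 7 and 3 lists and 142, 122 and 146 genes with diffSpliceDGE.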

How the results depend on the processing

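The alternatives that used only the M6-only lane (except for the genes called in M6 knockdown without a block), transcript shares, or genes other than those counted all or none, and size factors of the DESeq2 kind for gene lists, were added after seeing the data, and all others were planned. Over 170 named results and 34 settings, 2571 values kept their direction and side of the threshold, 80 lost a call, 54 gained one and 15 reversed, and 117 results kept both in every setting. Unless the setting itself tests fewer genes or uses fewer samples, the cause was not tested. Where a replicate left out leaves a group with 1 sample, the spread is pooled and the lone sample is assumed to vary like the others. Depth was least in M27H4 overexpression replicate 1, at 34892461 counts. Esrp2 in 3T3-L1 rested on 36 to 85 counts per replicate, which may include reads carried from the M6 libraries of the same lanes. Carry-over in that direction was not tested.

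Genes called in M6 knockdown numbered 29, and 233 with DESeq2, 64 with limma voom, 64 with no filter, 0 with only the M6 libraries, 559 with columns as libraries, which counts repeat runs as samples, and 147 with M6 library codes as replicates. In M27H4 overexpression they numbered 2, and 6 with DESeq2 and 1 with limma voom, with only that line, with columns as libraries, with technical replicate 1 alone or without the genes counted all or none. In 3T3-L1 they numbered 1, and 12 with DESeq2, 3 with limma voom, 2 with no filter, 4 with only that line, 2 with columns as libraries and 2 with technical replicate 1 alone. For the difference between overexpression effects they numbered 1, and 11 with DESeq2 and 0 with limma voom, size factors of the DESeq2 kind, only these lines, columns as libraries, technical replicate 1 alone or without the genes counted all or none. Between the lines 6420 became 9768 with columns as libraries. For knockdown minus overexpression 6 became 89 with DESeq2, 26 with no filter, 3 with only the lines compared and 169 with columns as libraries. Shared calls of the overexpression lines went from 1 to 0 with only the lines compared, and opposite calls of knockdown and overexpression from 0 to 2 with DESeq2 and 1 with columns as libraries.

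No lane sets the M6 pairs apart, since both have columns in the M6-only lane. There the library codes were close within a number, at 143700 and 143702 for replicate 1 and 145090 and 145091 for replicate 2. The other replicate 2 columns carried 143062 in knockdown and 145094 in control, in different lanes. Whether the M6 numbers stand for pairs is not stated. The correlation of the M6 pairs, 0.577, is a single value, since with 2 replicates per group both pairs have the same correlation by construction. With the replicate block the calls were 293 in M6, 424 there with only the M6-only lane as well, 1 in M27H4, 0 in 3T3-L1, 0 for the difference between overexpression effects, 112 for knockdown minus overexpression and 0 shared. In M6 the block also called G2/M genes (adjusted p = 0.047, and 0.616 with an estimated correlation), and for knockdown minus overexpression the histones (0.0499, and 0.824 with an estimated correlation). Transcript usage by diffSpliceDGE with the block gave 53 genes in M6 (9 shared with the fit without it), 104 in M27H4 (54 shared), 67 in 3T3-L1 (21 shared), 87 for the difference between overexpression effects (57 shared) and 63 for knockdown minus overexpression (44 shared), and the share test with it gave 2 in M6, 0 in M27H4, 1 in 3T3-L1, 1 for the difference between overexpression effects and 1 for knockdown minus overexpression. Of the named genes and the gene lists in M27H4, 3T3-L1 and their difference, the replicate block changed no other call than those given with their results. The block was not fitted between the lines, since the same replicate number in M6 and in M27H4 stands for different cultures.

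Of the lists, 10 were called in M6, and 1 with an estimated correlation and 1 by fry. In M27H4 overexpression 7 became 0 and 0, for the difference between overexpression effects 7 became 0 and 0, between the lines 9 became 0 and 15, and for knockdown minus overexpression 13 became 1 and 1. In 3T3-L1 0 became 3 with the replicate block, 1 with only that line and 1 with size factors of the DESeq2 kind.

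Transcript usage by diffSpliceDGE called 20 genes in M6, against 61 with a filter at 10 counts, 314 in the M6-only lane, 2 by the share test and 45 by it in the M6-only lane. In M27H4 151 became 55 with a gene-level F test, 61 with the filter and 0 by shares. In 3T3-L1 41 became 24 with the F test, 83 with the filter and 17 by shares. For the difference between overexpression effects 106 became 45 with the F test and 2 by shares. Between the lines 208 became 502 in the M6-only lane and 107 by shares. For knockdown minus overexpression 133 became 52 with the F test, 81 with the filter, 312 in the M6-only lane, 2 by shares and 17 by shares in the M6-only lane.

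With a replicate left out, the calls ran from 6 (without control replicate 1) to 60 (without control replicate 2) in M6, and were 11 without knockdown replicate 1 and 47 without knockdown replicate 2. They ran from 1 (without overexpression replicate 2) to 2 in M27H4 and from 0 (without control replicate 2) to 5 (without overexpression replicate 1) in 3T3-L1, where control replicate 1 left out gave 2. For the difference between overexpression effects they ran from 0, without either 3T3-L1 control or without M27H4 control or overexpression replicates 2 and 3, to 5 without 3T3-L1 overexpression replicate 1. Between the lines they ran from 5256 to 6017. For knockdown minus overexpression they ran from 0 (without M6 knockdown replicate 1) to 26 (without M6 knockdown replicate 2), and were 3 without M6 control replicate 1, 22 without M6 control replicate 2 and 2 without M27H4 overexpression replicate 3. Shared calls ran from 0, without either 3T3-L1 control, to 1, and opposite calls stayed at 0. Lists ran from 6 (without control replicate 2) to 11 in M6, 2 to 12 in M27H4, 3 to 4 in 3T3-L1, 3 (without M27H4 overexpression replicate 2) to 11 (without M27H4 control replicate 3) for the difference, 8 to 11 between lines and 10 to 15 for knockdown minus overexpression. Genes with transcript usage called by diffSpliceDGE ran in M6 from 15 to 168 (without knockdown replicate 2), with 81 without control replicate 2, and in M27H4 from 50 (without overexpression replicate 3) to 121, with 74, 98 and 68 without control replicates 1, 2 and 3. In 3T3-L1 they ran from 9 (without control replicate 2) to 26 (without control replicate 1), with 20 and 22 without overexpression replicates 1 and 2. For the difference they ran from 15 to 119, with 15 to 27 without any 3T3-L1 replicate and 62 without M27H4 overexpression replicate 3. Between the lines they ran from 83 (without M6 control replicate 1) to 209, with 95, 101 and 93 without M27H4 control replicates 1, 2 and 3. For knockdown minus overexpression they ran from 48 (without M6 knockdown replicate 1) to 138, with 61 and 71 without M6 control replicates 1 and 2.

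On the log2 scale Esrp2-as in M6 was -1.95 with DESeq2 and -1.79 with columns as libraries, both called, and ran from -2.35 to -1.65 with a replicate left out. In M27H4 it was 5.67 with only that line and 5.40 with the replicate block, neither called, and ran from 5.32 to 6.03. In 3T3-L1 it was 7.09 with the replicate block, not called, and ran from 6.83 to 7.32. Esrp2 ran from -0.26 to -0.04 in M6, from -0.27 to 0.11 in M27H4, reversed without control replicate 2 (0.02) or overexpression replicate 1 (0.11), and from 0.06 to 0.22 in 3T3-L1. With technical replicate 1 alone Esrp2 reversed to -0.15 in 3T3-L1 and to 0.12 for the difference between overexpression effects, and for knockdown minus overexpression it ran from -0.29 to 0.083. In M6 Rps4x ran from -0.66 to 0.14, Rps20 from -0.74 to 0.16, Rpl23 from -0.80 to 0.28, Hist4h4 from -1.15 to 0.22 and Hist1h4f from -0.86 to 0.071, all positive without control replicate 2, and Atf3 from -2.31 to 0.53, positive without control replicate 1. In M27H4, without control replicate 1, Sod2 ran up to 0.001 from -0.86 and Cxcl5 up to 0.47 from -2.29. In 3T3-L1 Hist2h2bb ran from -0.95 to 0.033, Rnu11 from -0.81 to 0.049 and Snora73b from -0.12 to 0.83.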

Other observations

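The genes of the next sentences, and the transcripts of Cd44 beyond Cd44-201, were chosen only after their values were seen, and no test of an explanation was run on them. Other genes called higher in M6 knockdown by edgeR were Areg, the EGF receptor ligand amphiregulin, at a log2 change of 1.95 (adjusted p = 0.0116), Hgf, hepatocyte growth factor, at 1.62 and the drug efflux transporters Abcb1b and Abcb1a at 2.16 and 2.07. Also called higher were Rapgef3 at 2.10, Slc4a11 at 1.82, Col8a1 at 1.65, Ikbke, a kinase of innate immune signalling, at 1.51, Dcbld2 at 1.30 and Ephx1, microsomal epoxide hydrolase, at 1.29. Gm26083, a small Cajal body RNA, was called lower at -5.79 (adjusted p = 0.00144), with 13.8 and 5.55 CPM in the controls and 0.148 and 0.190 CPM in the knockdown.

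The shares of Cd44 transcripts in M6 are given here as values, since the planned diffSpliceDGE test gave Cd44 an unadjusted p of 0.902 and an adjusted p of 1 in M6 knockdown. Cd44-202, with 14 exons, made up 15.2% ± 2.23 (SD, n = 2) in control and 57.4% ± 0.160 (n = 2) in knockdown. Cd44-201, with 19 exons, ran from 10.6 to 20.5% over the control columns and from 1.94 to 3.18% over the knockdown columns. Cd44-208, with 16 exons, stood at 19.2% ± 5.63 (n = 2) in control and 6.59% ± 1.36 (n = 2) in knockdown, and Cd44-205, with 12 exons, at 26.4% ± 3.44 (n = 2) and 14.9% ± 1.74 (n = 2). Cd44-203, with 9 exons, stayed near 3.87% in control and 4.39% in knockdown, while it made up 80.1% in M27H4 control. In the M6-only lane limma on shares gave Cd44-208 at 21.6% ± 2.13 (n = 2) in control and 6.02% ± 0.546 (n = 2) in knockdown, with a p of 0.00759 adjusted over the list alone and 0.0809 over all genes. The M6 columns held 5666 to 18440 counts of Cd44.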
